A study of Mus musculus with 96 samples.

How the data were processed

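RNA was measured by sequencing in the livers of 96 male mice, 48 with floxed Rbbp5 alleles and no Cre recombinase (Flox) and 48 littermates that also carried Cre under the albumin promoter, which deletes the floxed segment in hepatocytes (LKO). Each genotype held 2 libraries at each of 24 time points, taken every 2 h from circadian time (CT) 0 to 46. The replicate letters were A in 44 libraries, B in 48 and C in 4. Which part of Rbbp5 is floxed is not given in the sources used here.

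The authors deposited 1 table of gene-level values, which hold fragments mapped to a gene, scaled by its length and by the depth of the library (FPKM). The unit was read from the values and from the tools that the labels name, because the header gives none. Per the labels the authors used FastQC, Trimmomatic, HISAT2 and Cufflinks with the mouse build mm10, and the versions are not given in the sources used here. Raw counts were not used here. The table held 13094 entries, of which 65 repeat a symbol and 21 carry a number in place of a symbol, as date conversion in a spreadsheet leaves it. These 21 could not be matched to genes. Of the entries 569 had a value of 0 in at least 1 library, and the lowest mean was 0.0667 FPKM.

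Absolute depth is unknown, since FPKM values give no counts, and no counting intervals or detection floors are given for that reason. Totals ran from 313376 to 498760 FPKM per library. A relative depth was estimated from the steps between the smallest values below 0.3 FPKM in each pair of libraries. A clear step was found in 2931 of 4560 pairs, and 87.6% of these lay within 0.03 on the log2 scale of the fitted depths. On 12 simulated libraries with 4000 genes the largest error of a log2 depth was 0.002.

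Values were analysed as log2(FPKM + 1) for the 9901 entries with a mean of at least 1 FPKM. The mean was taken over all 96 libraries, so a gene that is low elsewhere could enter through a few libraries in which it is high. Settings that left out libraries kept this selection of genes. Linear models were fitted in limma 3.58.1 under R 4.3.3 with an intensity trend and robust variance moderation, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All gene tests were two-sided moderated tests or F tests. The genotype comparison held a factor for the 24 time points and a genotype term. The rhythm model held a mean and cosine and sine terms of 24 h and 12 h for each genotype, with F tests of each period within each genotype and of the difference between genotypes. An amplitude is the fitted half-range of a period on the log2 scale, and its peak is given as CT. The share with a lower amplitude in LKO was counted over the genes whose cosine and sine terms, averaged over both genotypes, passed an F test for that period, and the amplitude change was measured along this average.

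Before the data were examined, 44 gene lists of pathways, complexes and cell types were fixed, of which 43 had at least 3 tested members. Genotype differences of lists were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether the members move, on balance, in a common direction. For the 12 h rhythm each list was scored per library as the mean of its members after scaling each to an SD of 1. The F statistic of the score was compared with 100000 permutations, one-sided on F, so that the smallest p the permutations can give is 1e-05. P-values of the planned lists were adjusted over the 43 lists. Lists of alveolar macrophage markers, lung epithelial markers, Y-linked genes and ribosomal RNA precursor and small nucleolar RNA genes were added after the data had been seen. Their p-values were adjusted apart, only over the added lists with at least 3 tested members. Of the lung epithelial list 1 of 12 genes was tested, with a log2 difference of -0.46 between genotypes.

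The genes named in the text follow a rule fixed before the data were examined. Rbbp5 comes first. For the genotype comparison the rule names the 10 largest positive and the 10 largest negative log2 fold changes past the threshold, with the same sign on both days and a mean of at least 2 FPKM in at least 1 genotype. For the 12 h rhythm it names the 8 smallest p-values in each genotype with an amplitude of at least 0.2. For a difference of rhythms it names the 8 smallest p-values that pass, or the 4 smallest if none passes. For the 24 h rhythm it names the core clock list and the 6 smallest p-values in Flox outside it. For each list it names up to 4 members with the smallest p, with Xbp1, Hspa5, Atf6 and Manf always among the 12 h values. Some members that the rule names are not reported. Gene models without a proper name were counted and not named, which passed over 1 lower entry. The deposited symbols were matched to GENCODE M21 positions on mm10 for 420 of 424 named genes.

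The alternatives included other pseudocounts, filters, scalings, thresholds, periods and time models, library weights, leaving out each letter, each time point and each day, time point means and ranks. Settings without the 6 LKO libraries of CT42 to CT46, or without these time points in both genotypes, were added after the data had been seen. So were a linear trend and a covariate for the ribosomal RNA precursor Rn45s on top of the former. Results were compared over 100 groupings of the libraries that kept time points, and rhythm results over 100 orders of the time points, with the real one included in each. The models were tested on simulated data, with noise drawn independently for each gene and library. Structure shared by many genes of a library was not simulated, so the rates below need not hold for the real data. Of 50 genes per size with a simulated genotype difference, 64% were called at 0.25 on the log2 scale, 94% at 0.5 and 100% at 1, with 9 false calls among 9701 unchanged genes. Of 50 genes per size with a simulated 12 h rhythm in Flox, 30% were called at an amplitude of 0.2, 90% at 0.4, 86% at 0.6 and 100% at 0.8. A simulated 12 h difference between genotypes was called in 12% of 25 genes at 0.2, 72% at 0.4, 64% at 0.6 and 96% at 0.8. Of 200 simulated list scores without a rhythm, 7.5% had a p below 0.05. No library was left out of the primary tests, and 0 measurement columns were unused. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.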

Results

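Liver RNA of 96 male C57BL/6J mice aged 3 to 4 months was measured, from 48 Flox mice and 48 littermates with Rbbp5 deleted in hepatocytes (LKO). RBBP5 is a shared subunit of the complexes that methylate histone H3 at lysine 4. The mice were held for 2 weeks in 12 h of light and 12 h of darkness and then for 24 h in constant darkness before sampling. The series asks what RBBP5 does for gene expression and for rhythms of about 12 h in the liver. Total FPKM per library averaged 398191 ± 40597 (SD, n = 48) in Flox and 389597 ± 35980 in LKO. Relative depth ran from 0.708 in the Flox library of CT36 with letter A to 1.698 in the LKO library of CT32 with letter B. Its mean was 0.965 ± 0.122 (SD, n = 48) in Flox and 1.093 ± 0.174 in LKO, and the log2 depths differed (two-sided permutation p = 5e-05). Labels of sequencing batch or date are not given in the sources used here.

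Rbbp5 itself (ENSMUSG00000026439.14, mm10 chromosome 1, 132477365 to 132505659, plus strand) measured 3.27 ± 0.586 FPKM (SD, n = 48) in Flox and 2.46 ± 0.774 FPKM in LKO. The log2 fold change was -0.32 (SE 0.05, adjusted p = 2.43e-07, limma). Flox libraries ranged from 1.55 to 4.32 FPKM and LKO libraries from 1.61 to 4.23, so the ranges overlapped. The value counts the whole gene in whole liver, with any segment that stays after deletion and with cells that express no albumin. Rbbp5 was higher in LKO at 5 of the 24 time points. At CT42 to CT46 it measured 3.79 ± 0.399 FPKM (n = 6) in LKO and 2.71 ± 0.718 in Flox, against 2.51 ± 0.684 and 3.49 ± 0.488 (n = 24) at CT0 to CT22. The lowest Flox value, 1.55 FPKM, came from CT42 with letter B, where the ribosomal RNA precursor Rn45s measured 17769 FPKM. Without the 6 LKO libraries of CT42 to CT46 the log2 fold change was -0.42.

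**Figure D1:**
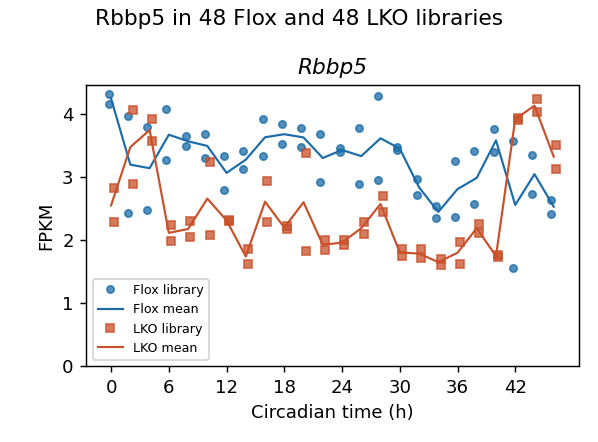
Rbbp5 in each of the 96 libraries, in FPKM on a linear axis, against circadian time in hours, with 1 point per library and a line through each genotype's mean of 2 libraries. LKO lies below Flox at most time points and above it at CT42 to CT46, where the LKO mean is 3.79 FPKM.

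The LKO libraries of CT42 to CT46 held transcripts of macrophages far above any other library. Ear2, an eosinophil-associated ribonuclease of alveolar macrophages, measured 1081 ± 312 FPKM (SD, n = 6, from 672.6 to 1387) in them, 2.25 FPKM in Flox at the same times and at most 6.36 FPKM in LKO before CT42. Lyz2, the macrophage lysozyme, measured 5834 ± 1655 FPKM against 31.01 in Flox, and Ccl6, a macrophage chemokine, 733 FPKM against 2.49. The Kupffer cell markers Clec4f (11.27 FPKM against 16.02) and Cd5l (12.2 FPKM against 18.3) did not share this rise. Cd68 of the same list did (192 FPKM against 4.815). Of 27 tested alveolar macrophage markers, a list added after the data had been seen, the median log2 difference at CT42 to CT46 was 5.34. Flox livers expressed 16 of the 27 at 1 FPKM or more, and 7 belong to other lists used here. These are Marco and Lyz2 among Kupffer cell markers, Itgax and Cd9 among those of monocyte-derived macrophages, Krt19 among those of cholangiocytes, Cidec in fatty acid synthesis and F7 in complement and coagulation. The 6 libraries were set apart by their labelled times after the data had been seen, and counts of genes higher and lower in LKO are also given without them.

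**Figure D2:**
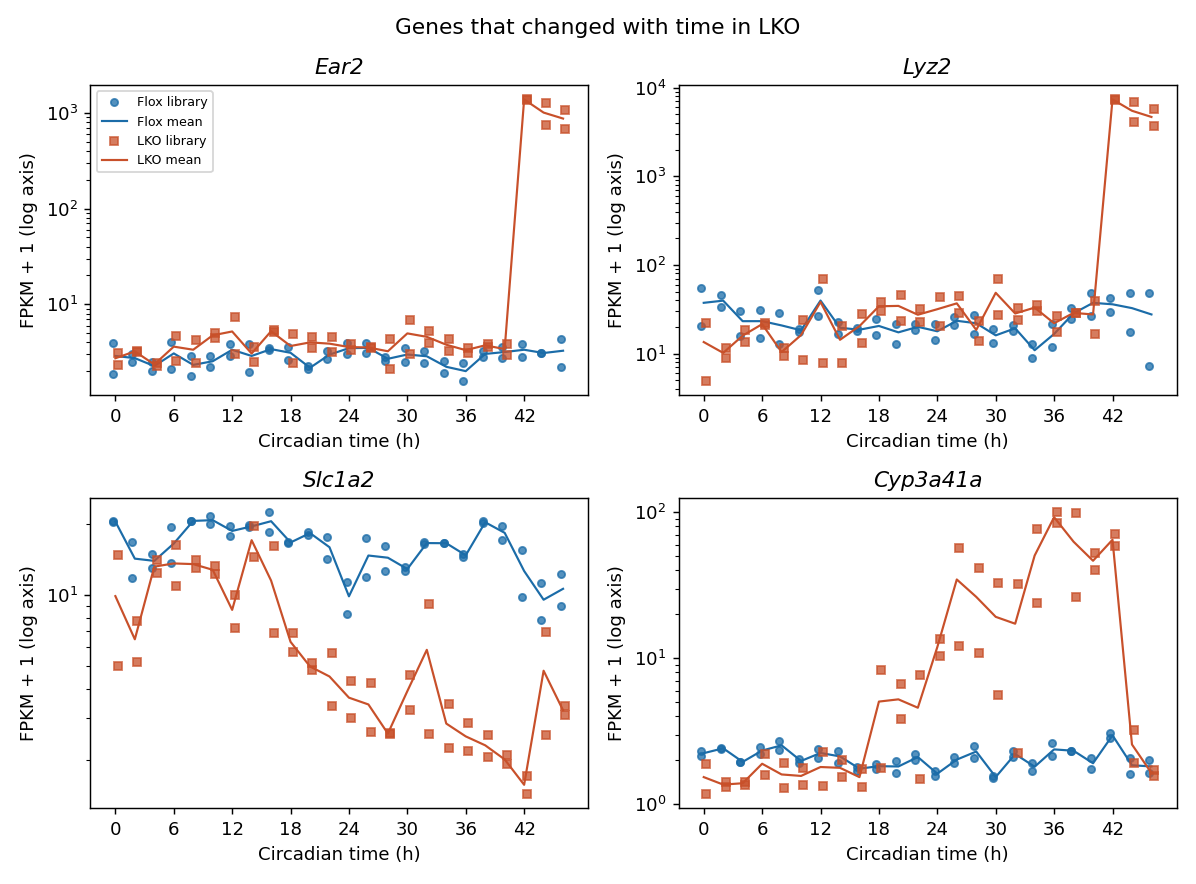
FPKM + 1 on a log axis against circadian time in hours for Ear2, Lyz2, Slc1a2 and Cyp3a41a, with 1 point per library and lines through the means of 2 libraries per genotype. Ear2 and Lyz2 stand high in LKO at CT42 to CT46 (mean 1081 and 5834 FPKM), while the mean of Slc1a2 is lower in LKO than in Flox at each time point.

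Between genotypes Scgb1c1 and Ptgds, which Flox liver hardly expresses, had the largest positive log2 fold changes. Scgb1c1, a secretoglobin (chromosome 7, 140845547 to 140846769), measured 0.124 ± 0.167 FPKM (SD, n = 48) in Flox and 103 ± 201 in LKO, with a log2 fold change of 3.35 (SE 0.41, adjusted p = 2.93e-10) and a higher value at 24 of 24 time points. Ptgds, a prostaglandin D synthase (chromosome 2, 25466709 to 25470046), measured 0.595 FPKM in Flox and 29.7 in LKO (2.40, SE 0.30, 22 time points). LKO means were 3.16 FPKM of Scgb1c1 and 1.84 of Ptgds at CT0 to CT22, 197 and 64.4 at CT24 to CT40 and 219.7 and 36.89 at CT42 to CT46. The last means came from CT42, as the 4 LKO libraries of CT44 and CT46 held at most 4.91 FPKM of Scgb1c1 and 6.75 of Ptgds. The surface protein gene Ly6d (2.31, SE 0.23), the interferon-inducible Ifi27l2b (2.19, SE 0.16) and the calcium binding S100a11 (2.11, SE 0.18) were each higher at 24 time points. S100a11 reached 367 FPKM in the LKO libraries of CT42 to CT46, and its log2 fold change without them was 1.72. Sprr1a, an envelope protein gene of squamous epithelia (2.08), Cib3 (2.04), the glutathione transferase Gstm3 (1.94, 37.7 to 194 FPKM) and the noncoding RNA Meg3 (1.83) were higher at 23 time points each, and Mup6 (1.83) at 19.

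The largest negative changes held metabolic and secretory genes of hepatocytes. Slc1a2, a glutamate transporter of pericentral hepatocytes, measured 15.1 ± 3.73 FPKM (SD, n = 48) in Flox and 5.71 ± 4.91 in LKO (-1.59, SE 0.12, adjusted p = 1.49e-17) and was lower at each of the 24 time points. Its LKO mean was 9.18 FPKM at CT0 to CT22 and 2.24 at CT24 to CT40, while Flox measured 17.0 and 14.3. Fitm1, which serves lipid droplet formation, measured 44 FPKM in Flox and 19.1 in LKO (-1.64, SE 0.22, adjusted p = 1.74e-09). Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, measured 141 and 67.8 FPKM (-1.21, SE 0.16, adjusted p = 1.03e-09). Hsd3b5, a male-biased steroid dehydrogenase, fell by 1.26 on the log2 scale, the drug-metabolising Cyp2c29 by 1.18, Mia2 by 1.19 and the Golgi protein gene Tgoln2 by 1.16. The major urinary protein genes Mup16 (-1.41), Mup17 (-1.19) and Mup11 (-1.19) were lower at 20 or more time points each. Values of near-identical paralogs (the Mup, Gstm, Cyp2c and Cyp3a families, Tgoln, Saa and class II genes) are uncertain, since reads can be shared among them.

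Over all 9901 genes 3897 were higher and 1896 lower in LKO at the threshold. Without the 6 LKO libraries 3140 were higher, 3004 of them shared, and 2970 lower, 1772 of them shared. The direction of the whole depended on scaling, because 67.3% of the called genes were higher as deposited, 60.0% after median-ratio scaling and 45.0% after quantile normalization. Without letter B, which holds 48 of the 96 libraries, the counts were 2077 higher and 788 lower. They also depended on the day, with 2504 higher and 4366 lower on the first day alone. On the second day alone 900 were lower, while the count of higher genes stayed within 1.5 times of 3897, so the balance of directions turned between the days.

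Genes of hepatocyte metabolism were lower in LKO. Of 27 genes of the urea cycle and amino acid breakdown 23 fell and 0 rose (24 and 0 adjusted over the list alone), with a median log2 fold change of -0.33. Oat, an ornithine aminotransferase, measured 270 ± 78.7 FPKM (SD, n = 48) in Flox and 154 ± 104 in LKO (-1.08, SE 0.13, lower at 22 time points), and Mat1a, which makes S-adenosylmethionine, 465 and 292 FPKM. Of 30 fatty acid oxidation and ketogenesis genes 23 fell and 3 rose (23 and 3 adjusted over the list alone, median -0.28). Of 24 bile acid genes 17 fell and 2 rose (17 and 2 adjusted over the list alone, median -0.41), with Cyp27a1, a sterol hydroxylase, at 160 and 117 FPKM. Of 18 genes of gluconeogenesis and glycogen metabolism 13 fell and 0 rose (13 and 0 adjusted over the list alone, median -0.31), with Fbp1, fructose bisphosphatase, at 369 and 224 FPKM. Camera adjusted p-values for these 4 lists ran from 4.47e-10 to 1.07e-05, while adjusted p = 0.201 with an estimated correlation for the amino acid, bile acid and gluconeogenesis lists and 0.239 for fatty acid oxidation. Their medians were -0.38, -0.51, -0.56 and -0.53 at CT0 to CT22, -0.16, -0.11, -0.13 and -0.09 at CT24 to CT40 and -0.86, -0.24, -0.59 and -0.45 in the LKO libraries of CT42 to CT46. With these libraries left out 19, 22, 17 and 12 of their genes fell and 0, 2, 2 and 0 rose. The ribosomal RNA precursor Rn45s measured 4500 ± 5091 FPKM (SD, n = 24) in LKO and 1407 ± 475 in Flox at CT0 to CT22, and 3046 and 2452 FPKM (n = 18) at CT24 to CT40. At CT42 to CT46 it ran from 1658 to 4644 FPKM in LKO and from 1259 to 17769 in Flox, so differences there may also carry the state of the Flox libraries. With log2 Rn45s as a covariate besides, camera adjusted p-values of the 4 lists were 6.32e-06, 1.8e-07, 1.12e-05 and 0.000396, while the genes lower over the whole set went from 2970 to 1306, with 1298 shared. Lipid synthesis was also lower, with 10 of 24 genes of fatty acid and triglyceride synthesis falling and 3 rising (10 and 3 adjusted over the list alone), camera adjusted p = 0.00235, adjusted p = 0.463 with an estimated correlation, and 12 falling and 2 rising without the 6 LKO libraries. Its examples are the desaturase Fads2 (-0.91, SE 0.20) and the regulator Srebf1 (-0.41, SE 0.09). The median of this list was -0.54 at CT0 to CT22 and 0.10 at CT24 to CT40, and its call was lost after quantile normalization (adjusted p = 0.0809, range over its alternatives 0.000755 to 0.463).

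Zonal, secretory and drug-metabolising genes followed the same direction. Of 14 pericentral hepatocyte genes 10 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.38), with Cyp2e1, an ethanol-oxidising P450, at 2121 ± 716 FPKM (SD, n = 48) in Flox and 1202 ± 535 in LKO (-0.90, SE 0.11). Camera gave adjusted p = 1.16e-06 for it, and adjusted p = 0.201 with an estimated correlation. Of 28 complement and coagulation genes 19 fell and 0 rose (19 and 0 adjusted over the list alone, median -0.25), among them F2, prothrombin (475 to 331 FPKM), with camera adjusted p = 1.8e-08 and adjusted p = 0.216 with an estimated correlation. Of 22 xenobiotic P450 genes 14 fell and 2 rose (14 and 2 adjusted over the list alone, median -0.26), with camera adjusted p = 2.43e-05 and adjusted p = 0.201 with an estimated correlation. Of 15 hepatocyte markers 10 fell and 1 rose (10 and 1 adjusted over the list alone, median -0.31), with Hnf4a, a nuclear receptor that maintains hepatocyte identity, at 113 and 86.0 FPKM. Camera gave adjusted p = 0.000405 for the markers, adjusted p = 0.201 with an estimated correlation, and the call was lost after quantile normalization (adjusted p = 0.218, range over its alternatives 6.53e-07 to 0.218). The medians of these 4 lists were -0.29, -0.24, -0.31 and -0.37 at CT0 to CT22, -0.36, -0.14, -0.19 and -0.12 at CT24 to CT40 and -0.94, -0.62, -0.76 and -0.66 in the LKO libraries of CT42 to CT46. With these 6 libraries left out 9, 18, 11 and 8 of their genes fell and 1, 1, 2 and 2 rose. Of 15 periportal genes 7 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.00732, adjusted p = 0.404 with an estimated correlation). Arg1, the arginase of the urea cycle, was lower in LKO over both days (609 to 502 FPKM, -0.31, SE 0.07) but not on the first day (0.0276). The periportal median was -0.13 at CT0 to CT22, 0.06 at CT24 to CT40 and -0.68 at CT42 to CT46, and the call was lost without the 6 LKO libraries (7 lower and 1 higher, adjusted p = 0.182, range over its alternatives 0.00189 to 0.404) and after quantile normalization (0.321).

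Proteasome and acute phase genes gave smaller or mixed differences. Of 31 proteasome genes 14 fell and 3 rose (14 and 3 adjusted over the list alone, median -0.11), camera adjusted p = 0.00474, adjusted p = 0.581 with an estimated correlation and 0.125 with fry (range over its alternatives 0.000715 to 0.581). Psmd11 (-0.39, SE 0.08) and Psmc1 (-0.34, SE 0.07), both subunits of the regulatory particle, were among those that fell, and the median of the list was 0.28 at CT42 to CT46. If the 6 LKO libraries are left out, 18 fell and 3 rose. Of 30 acute phase genes 13 fell and 7 rose (14 and 8 adjusted over the list alone), camera adjusted p = 0.0122 and adjusted p = 0.582 with an estimated correlation. Saa3, a serum amyloid of macrophages and other cells, rose by 1.83 on the log2 scale (SE 0.24, 21.6 to 72.4 FPKM), while Saa4 (-0.81) and the protease inhibitor Serpina3k (-0.68) fell. The median of the acute phase list was -0.21, its mean was 0.03 and camera called it lower, so mean and test differed in sign. Its median went from 0.22 at CT0 to CT22 to -1.02 at CT42 to CT46, and the call was lost without the 6 LKO libraries (12 lower and 9 higher, adjusted p = 0.435), after quantile normalization (0.708) and with fry (0.182), with a range over its alternatives of 0.002 to 0.708.

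Translation, RNA processing and growth genes were higher in LKO. Of 65 cytosolic ribosomal protein genes 54 rose and 0 fell (55 and 0 adjusted over the list alone, median 0.34), camera adjusted p = 1.8e-08 and adjusted p = 0.463 with an estimated correlation. Rps12 measured 118 ± 36.9 FPKM (SD, n = 48) in Flox and 190 ± 59.6 in LKO (0.67, SE 0.08, higher at 22 time points), and Rpl14 106 and 176 FPKM. Of 30 cell cycle genes 11 were tested, and each of the 11 rose (11 adjusted over the list alone, median 0.46), camera adjusted p = 0.00029 and adjusted p = 0.404 with an estimated correlation. Members low in Flox could enter the test through LKO libraries in which they were high, so the filter can favour this count. The cyclin Ccnd1 measured 5.26 ± 3.08 FPKM in Flox and 18.1 ± 10.8 in LKO (1.48, SE 0.15, 23 time points), and Birc5, survivin, was higher at 24 (0.82, SE 0.09). The cell cycle median was 0.09 at CT0 to CT22, 0.44 at CT24 to CT40 and 1.82 at CT42 to CT46. Of 48 mRNA splicing genes 28 rose and 0 fell (28 and 0 adjusted over the list alone, median 0.22), among them the splicing kinase Clk1 (7.89 to 15.3 FPKM), camera adjusted p = 0.00203 and adjusted p = 0.582 with an estimated correlation. The splicing median was 0.02 at CT0 to CT22 and 1.16 at CT42 to CT46, and its call was lost without the 6 LKO libraries (22 higher and 11 lower, adjusted p = 0.0785, range over its alternatives 7.27e-05 to 0.582). In the same setting 50 ribosomal protein genes were higher and 2 lower, and 10 and 0 of the cell cycle.

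Stress and damage genes rose as well. Of 15 genes of the p53 and DNA damage response 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 0.47), camera adjusted p = 0.00109 and adjusted p = 0.385 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, measured 4.92 ± 5.68 FPKM (SD, n = 48) in Flox and 18.98 ± 24.15 in LKO (1.44, SE 0.20), with 72.0 FPKM in the LKO libraries of CT42 to CT46, and Bax, an apoptosis gene, rose by 0.68 (SE 0.08). Of 19 genes of the integrated stress response 13 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.26), camera adjusted p = 0.0134 and adjusted p = 0.477 with an estimated correlation. The cytokine Gdf15 measured 5.42 and 17.0 FPKM (55.6 in the LKO libraries of CT42 to CT46) and the transcription factor Atf3 rose by 1.31 (63.5 FPKM in those libraries), while Shmt2 of folate metabolism fell by 0.23. Of 16 fetal liver and hepatocyte stress genes 12 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.83), camera adjusted p = 1.39e-05 and adjusted p = 0.216 with an estimated correlation. Besides Ly6d and S100a11 they include S100a6 (1.26, SE 0.14) and the annexin Anxa5 (0.87, SE 0.10). Medians at CT42 to CT46 were 1.08 for p53, 1.05 for the integrated stress response and 2.44 for the fetal and stress genes, against 0.22, 0.11 and 0.42 at CT0 to CT22. Leaving out the 6 LKO libraries gave 10, 11 and 13 higher and 0, 2 and 0 lower genes in these 3 lists.

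Inflammatory and antigen presentation genes were higher, and most of these groups moved with the LKO libraries of CT42 to CT46. Of 28 interferon response genes 20 rose and 1 fell (21 and 1 adjusted over the list alone, median 0.22), camera adjusted p = 0.000968 and adjusted p = 0.404 with an estimated correlation. Usp18 (1.24 to 2.62 FPKM, 0.64, SE 0.07) and Xaf1 (0.56, SE 0.06), both induced by interferon, were higher at 24 time points, and the median of the list was 0.28 at CT0 to CT22 and 0.13 at CT42 to CT46. Of 22 genes of NF-kB and inflammatory signalling 18 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.57), camera adjusted p = 0.00343 and adjusted p = 0.535 with an estimated correlation. Members such as Tnf (33.9 FPKM in the 6 LKO libraries, 0.19 in other LKO libraries) and Ccl3 (79.0 and 0.30) entered the test through the 6 libraries. Their rise with all libraries was therefore given by the filter. The transcription factor Jun measured 4.604 and 17.17 FPKM (72.2 in the LKO libraries of CT42 to CT46), and the list's median was 0.11 at CT24 to CT40 and 2.57 at CT42 to CT46. Each of the 6 class II antigen presentation genes rose (6 adjusted over the list alone, median 0.95), camera adjusted p = 0.00122 and adjusted p = 0.404 with an estimated correlation. H2-Aa measured 18.1 ± 8.02 FPKM (SD, n = 48) in Flox and 48.1 ± 46.6 in LKO (1.07, SE 0.14), and the medians of the class II list were 0.72, 0.59 and 3.26 at CT0 to CT22, CT24 to CT40 and CT42 to CT46. Leaving out the 6 LKO libraries gave 17 interferon, 12 NF-kB and 6 class II genes higher and 1, 2 and 0 lower.

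**Figure D3:**
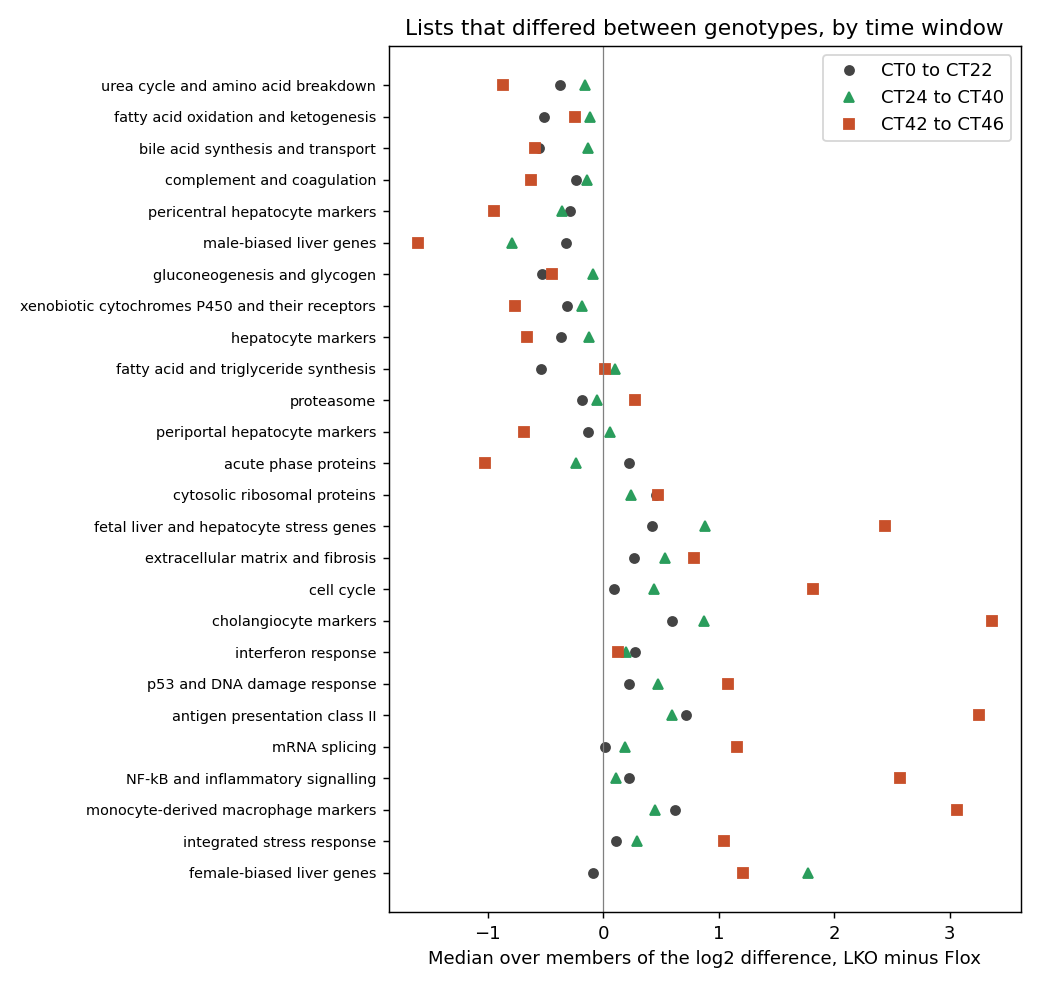
Median log2 difference of LKO minus Flox over the members of each of the 26 lists that passed the genotype test, as points for the LKO and Flox libraries of CT0 to CT22, CT24 to CT40 and CT42 to CT46. At CT42 to CT46 cholangiocyte (3.36), class II (3.26) and monocyte-derived macrophage markers (3.06) stand highest, and male-biased genes (-1.61) lowest.

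Among the marker lists of other cell types, those of bile duct cells and recruited macrophages passed camera as higher. Of 15 cholangiocyte markers 6 were tested, and each of the 6 rose (6 adjusted over the list alone, median 1.09), camera adjusted p = 0.000405 and adjusted p = 0.201 with an estimated correlation. Spp1, osteopontin, measured 22.1 ± 8.83 FPKM (SD, n = 48) in Flox and 102 ± 127 in LKO (1.76, SE 0.16), and Epcam, an epithelial adhesion gene (0.88, SE 0.13), was likewise higher at 24 time points. Of 8 markers of monocyte-derived macrophages 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.91), camera adjusted p = 0.00732 and adjusted p = 0.446 with an estimated correlation. Their Trem2, a lipid receptor, rose by 0.90 (SE 0.10), and the galectin Lgals3 by 1.51 (SE 0.23, 1.73 to 35.6 FPKM, 256 in the LKO libraries of CT42 to CT46). Of 17 genes of extracellular matrix and fibrosis 15 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.51), camera adjusted p = 0.00025 and adjusted p = 0.443 with an estimated correlation. The collagen Col1a1 measured 1.05 ± 0.950 FPKM in Flox and 4.41 ± 6.15 in LKO (1.16, SE 0.13), and Col1a2 (1.01, SE 0.11) was higher at 24 time points as well. Medians at CT0 to CT22 and CT42 to CT46 were 0.59 and 3.36 for cholangiocyte, 0.62 and 3.06 for macrophage and 0.27 and 0.78 for matrix genes. With the 6 LKO libraries left out 6, 7 and 13 of them rose and 0, 1 and 1 fell. Some members owe their place in the test to the 6 libraries, such as Itgax (62 FPKM there, 0.31 in other LKO libraries) and Epcam (17.4 and 1.05). Of 15 Kupffer cell markers 5 rose and 0 fell, and of 11 stellate cell markers 8 rose and 0 fell (the same counts adjusted over the list alone), and neither list passed camera (adjusted p = 0.279 and 0.0776). Without the 6 LKO libraries the stellate list passed (8 higher and 0 lower, adjusted p = 0.00949, range over its alternatives 4.22e-05 to 0.582), and 3 Kupffer cell markers were higher and 1 lower. Endothelial markers did not pass either (4 of 12 higher, 1 lower, or 4 and 0 adjusted over the list alone, adjusted p = 0.605), nor did those of T and NK cells (3 of 3 higher, 0.107) and neutrophils (4 of 4 higher, 0.111), with 3 and 4 adjusted over the list alone. Of these 3 lists 4, 3 and 2 genes were higher and 1, 0 and 0 lower without the 6 LKO libraries. At CT24 to CT40 each Kupffer cell (15 of 15), endothelial (12 of 12) and stellate cell marker (11 of 11) was higher in LKO. Their medians there were 0.52, 0.37 and 0.42, against 0.45 for monocyte-derived macrophage and 0.88 for cholangiocyte markers. Such counts were not particular to cell markers, as mRNA splicing (45 of 48) and ER translocation genes (48 of 56) were also mostly higher. Other lists were mostly lower, such as urea cycle and amino acid breakdown (7 of 27 higher). The share over all genes in this window is not given here.

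Male-biased liver genes were lower and female-biased ones higher in the LKO males. Of 20 male-biased genes 13 fell and 2 rose (13 and 2 adjusted over the list alone, median -0.68), camera adjusted p = 6.58e-06 and adjusted p = 0.239 with an estimated correlation. Besides Cyp7b1 and Hsd3b5, those that fell include Mup21 (198 ± 59.2 to 119 ± 54.5 FPKM, SD, n = 48). Of 9 female-biased genes 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.62), camera adjusted p = 0.0337 and adjusted p = 0.535 with an estimated correlation. The oestrogen sulfotransferase Sult1e1 measured 0.126 FPKM in Flox and 6.47 in LKO (1.77, SE 0.22, 23 time points). The P450 Cyp3a41a measured 1.08 and 18.2 FPKM (1.57, SE 0.27, 14 time points), with 1.44 FPKM in LKO at CT0 to CT22, 39.22 at CT24 to CT40 and 22.02 at CT42 to CT46, where the 4 libraries of CT44 and CT46 held at most 2.22. Female-biased medians were -0.09, 1.77 and 1.21 in those windows, and male-biased ones -0.32, -0.79 and -1.61. Leaving out the 6 LKO libraries gave 12 male-biased genes lower and 3 higher, and 0 and 7 female-biased ones. The female-biased call was lost without letter A (adjusted p = 0.0604), with a pseudocount of 0.1 (0.0552), with no filter on low values (0.104) and with a replicate block (0.0536), over a range of 2.3e-05 to 0.535. Cyp3a41a, Cyp17a1 and Cyp3a16 had negative log2 differences on the first day (-0.0715, -0.0866 and -0.0563).

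Of the 43 lists 13 rose and 13 fell by camera, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.201. With fry 19 were called higher and 11 lower. Without the 6 LKO libraries camera called 14 higher and 11 lower. Besides the estimated correlation, at least 1 alternative ended the calls of fatty acid synthesis, hepatocyte markers, periportal, acute phase, proteasome, mRNA splicing and female-biased genes. Some lists share members, such as Oat, Arg1, Cyp2e1, Cyp7b1, Cd24a and Cdkn1a. Over all alternatives run the number of lists called higher ran from 0 to 19, and lower from 0 to 14.

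In Flox livers, genes with a 12 h rhythm included those of protein folding and secretion that peaked near CT2 to CT3 and 12 h later. Hspa5, the ER chaperone BiP, had a 12 h amplitude of 0.64 (log2, SE 0.12, peak CT2.41, adjusted p = 0.00196), Hyou1, an ER chaperone, 0.68 (SE 0.11), Creld2 0.87 (SE 0.14) and Manf 0.58 (SE 0.10). Of the cytosolic chaperones Hsph1 had an amplitude of 0.83 (SE 0.11, adjusted p = 1.64e-06), Hspa8 0.74 (SE 0.11), Hsp90aa1 0.59 (SE 0.08) and Stip1 0.38 (SE 0.05). Xbp1 (0.19, adjusted p = 0.372) and Atf6 (0.22, adjusted p = 0.26), transcription factors of the unfolded protein response, did not pass. The smallest p-values came from Ciart (0.64, SE 0.07, peak CT10.6, adjusted p = 2.92e-09), a clock repressor, and Usp2 (0.70, SE 0.08, peak CT10.1, adjusted p = 2.92e-09), a deubiquitinase, followed by the genes above with Mypop (0.30) and Gmppb (0.47). Over all genes 176 passed the 12 h test in Flox, of which 91 peaked from 2 h to 4 h. Of 100 orders of the time points 9 gave as many, the real one included.

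As scores, 3 of the 43 lists had a 12 h rhythm in Flox. Cytosolic heat shock genes had an amplitude of 0.542 SD (n = 48, peak CT2.61, permutation p = 2e-05), ER chaperones and degradation 0.402 SD (peak CT2.62, p = 6e-05) and ER translocation with ER to Golgi transport 0.407 SD (peak CT2.65, p = 5e-05), each with an adjusted p of 0.00086. Among the members 10 of 20 heat shock, 8 of 40 ER chaperone and 9 of 56 translocation genes passed over all genes (15, 19 and 20 adjusted over the list alone). The core clock list held 6 of 17 members with a 12 h rhythm in Flox (8 adjusted over the list alone). Without letter A the adjusted p-values of the 3 scores were 0.0821, 0.0979 and 0.0821, so 0 lists passed, and without letter B they were 0.0486, 0.158 and 0.170, so 1 passed. Over their alternatives the adjusted p-values ran from 0.000215 to 0.0821, from 0.00103 to 0.158 and from 0.000215 to 0.170. The count of 176 genes went to 7 without letter A and 6 without B, which hold 44 and 48 of the 96 libraries. It went to 472 without CT0, 309 without CT10, 295 without CT20, 272 without CT28, 107 without CT2, 111 without CT4, 84 without CT34, 114 without CT40 and 81 without CT46.

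**Figure D4:**
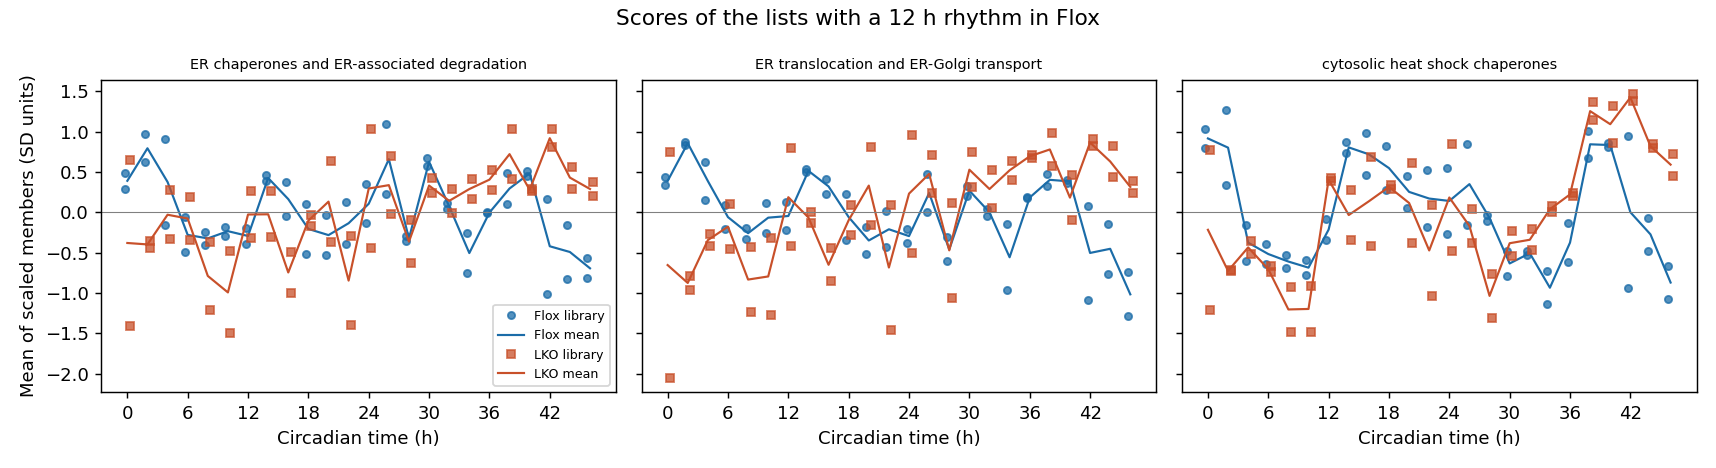
Scores of the cytosolic heat shock, ER chaperone and ER translocation lists, in SD units, against circadian time in hours, with 1 point per library and lines through the means of 2 libraries per genotype. In Flox the 3 scores have 12 h amplitudes of 0.542, 0.402 and 0.407 SD, and in LKO of 0.125, 0.0959 and 0.0626 SD.

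In LKO livers 933 genes passed the 12 h test, of which 569 peaked from 6 h to 8 h and 233 from 8 h to 10 h. Of 100 orders of the time points 33 gave as many, the real one included. A separate fit per genotype gave 0 such genes in LKO, as did time point means. B4galnt1, a ganglioside synthase, had an amplitude of 0.42 (peak CT7.56, adjusted p = 0.00457), Coq10b 0.41 (peak CT9.57, adjusted p = 0.00457) and the clock gene Per1 0.56 (peak CT8.88, adjusted p = 0.00575). Camkk2 (0.30), Rab20 (0.41), Ciart (0.38), Stat6 (0.30) and Sh3bp2 (0.52) complete the named genes. By list, 8 of 22 NF-kB genes passed over all genes (13 adjusted over the list alone) and 13 of 27 alveolar macrophage markers (23 adjusted over the list alone). In LKO 4 genes passed without the 6 libraries of CT42 to CT46, 2 of them among the 933, and the unadjusted count fell from 2499 to 791. The count was 7 without CT44, 501 without CT40, 529 without CT0, 541 without CT2, 562 without CT16, 618 without CT14, 1406 without CT22, 1743 without CT18 and 2042 without CT20. It was 0 without letter A and 0 without letter B, which hold 44 and 48 of the 96 libraries. In both genotypes 26 genes passed, against 16.6 expected if the calls were independent, and 0 without the 6 LKO libraries. Of the 43 list scores 0 had a 12 h rhythm in LKO by the permutation test, with 3 at an unadjusted p under 0.05.

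The difference of the 12 h rhythm between genotypes, the question of the series, was tested directly. Amplitudes of the heat shock, ER chaperone and ER translocation scores were 0.125, 0.0959 and 0.0626 SD in LKO, and the differences had permutation p-values of 0.0344, 0.0742 and 0.0251, with adjusted p-values of 0.155, 0.213 and 0.155. Of the 43 scores 0 differed after adjustment, with 10 at an unadjusted p under 0.05. Lower amplitudes in LKO were fitted for 18 of 20 heat shock, 33 of 40 ER chaperone and 43 of 56 translocation genes, and for 16, 34 and 48 of them without the 6 LKO libraries. These 3 lists were chosen for a 12 h rhythm in Flox, which by itself favours lower amplitudes in LKO, so the counts decide nothing. Among lists without such a rhythm the counts ran either way, as with ribosomal proteins (49 of 65) and NF-kB genes (1 of 22). Hspa5 had an amplitude of 0.18 in LKO (adjusted p = 0.561) and Hsph1 of 0.28 (adjusted p = 0.193), with an adjusted p of 0.130 for the difference of Hsph1. Manf (0.36, adjusted p = 0.0426), Creld2 (0.58, adjusted p = 0.0164) and Stip1 (0.20, adjusted p = 0.0229) had a called rhythm in LKO with all libraries, and none of these 3 did without the 6 LKO libraries (adjusted p = 0.253, 0.0665 and 0.145). The score of oxidative phosphorylation genes had an amplitude of 0.329 SD in Flox (peak CT10.2, adjusted p = 0.367), and its difference had a permutation p of 0.0131 (adjusted p = 0.150). Over the whole gene set 0 of its 56 members differed between genotypes, but 23 did adjusted over the list alone, and 20 without the 6 LKO libraries, while 50 and 47 had the lower amplitude in LKO. Adjusted over the list alone, heat shock genes gave 8 and 0 such differences and ER chaperone genes 0 and 0.

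By gene, limma called 0 of 9901 for a different 12 h rhythm, with 2553 at an unadjusted p under 0.05 and 1025 without the 6 LKO libraries. The smallest p-values belonged to Dedd2, Nde1, Sco2 and Trim25, from 8.15e-05 to 9.60e-05, each with an adjusted p of 0.130. Of 294 genes with a 12 h rhythm in the average of both genotypes, 54.1% had a lower amplitude in LKO. It was 63.5% of 271 without the 6 LKO libraries and 68.4% of 269 without CT42 to CT46 in both genotypes. The share lay under 50% without CT14 (46.6%), CT18 (43.4%), CT20 (33.6%) or CT22 (47.7%) after quantile (40.1%) or median-ratio scaling (44.5%) and on the second day alone (20.2%), while it was 74% with time point means and 87.5% without letter B. On the second day alone 4633 genes had a different rhythm, with library weights 4025, after quantile normalization 4 and after median-ratio scaling 1, and without CT10 there were 908, without CT18 3 and without CT20 2016.

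Core clock genes cycled with a 24 h period in both genotypes. Of the 17 clock genes 16 passed in Flox and 16 in LKO, and the exception was Rora (amplitude 0.23, adjusted p = 0.0753 in Flox, and 0.03, adjusted p = 0.932 in LKO). Arntl, which encodes the activator BMAL1, had an amplitude of 1.14 (log2, SE 0.06, peak CT23.1) in Flox and 1.16 (peak CT22.2) in LKO. Its targets Nr1d1 (2.26, peak CT7.37, and 2.12, peak CT7.46), Dbp (3.18, peak CT10.6, and 3.07, peak CT10.2) and Per2 (0.90, peak CT15.4, and 1.09, peak CT14.5) peaked in the same order in both genotypes. Arntl and Nfil3 differed between genotypes over all genes (adjusted p = 0.0377 and 0.0403), 0 of 17 did adjusted over the list alone, and neither did over all genes without the 6 LKO libraries. Outside the list Usp2, the tubulin Tubb2a, the P450 reductase Por and the choline kinase Chka (1.60 and 1.08) were among those with the smallest p-values in Flox. Over all genes 2699 had a 24 h rhythm in Flox and 4901 in LKO, with 1489 in both, against 1336 expected if independent. These counts were 3480, 2647 and 1404 without the 6 LKO libraries. Without letter A they were 1363 in Flox and 2060 in LKO, and without letter B 595 and 2784.

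**Figure D5:**
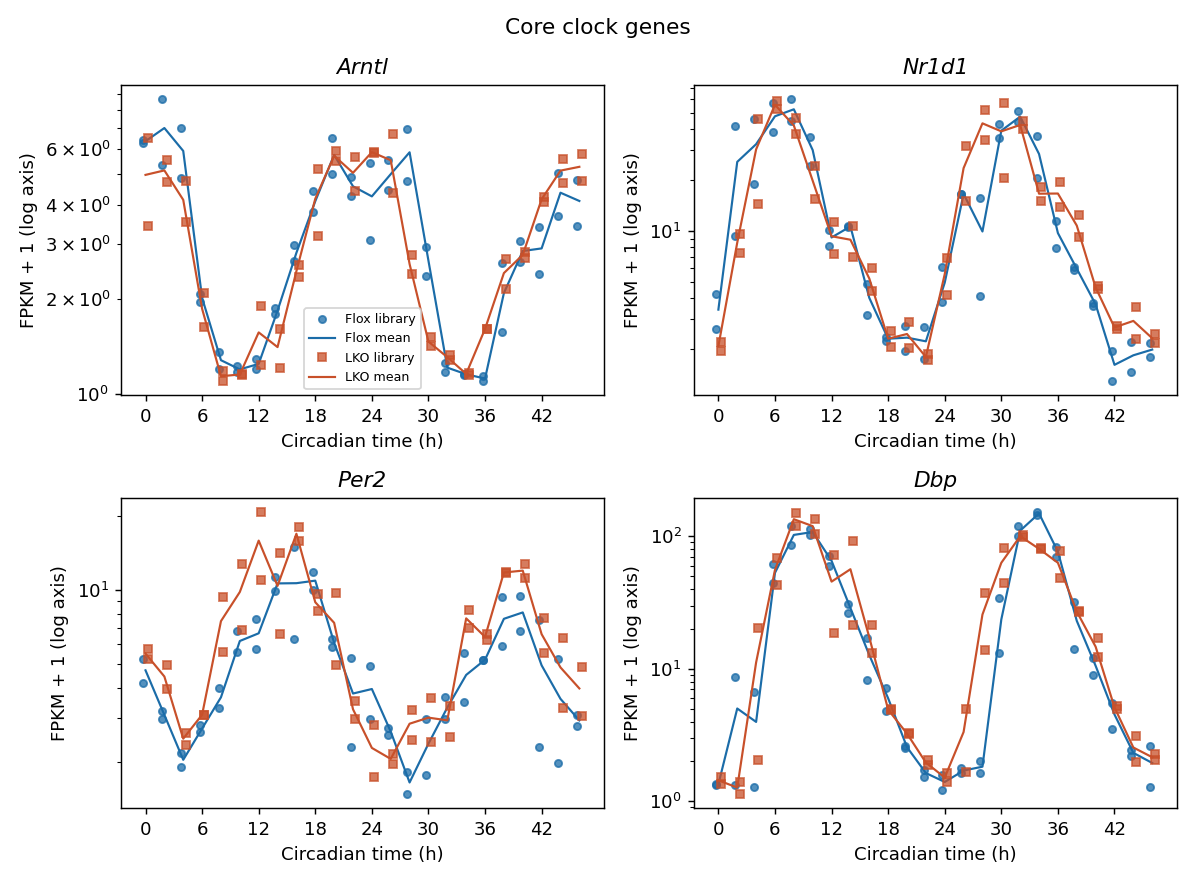
FPKM + 1 on a log axis against circadian time in hours for Arntl, Nr1d1, Per2 and Dbp, with 1 point per library and lines through the means of 2 libraries per genotype. Fitted peaks lie at CT23.1, CT7.37, CT15.4 and CT10.6 in Flox and at CT22.2, CT7.46, CT14.5 and CT10.2 in LKO.

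Between genotypes 1968 genes differed in their 24 h rhythm with all libraries, and 26 of them did without the 6 LKO libraries of CT42 to CT46. Cryl1, a sugar acid dehydrogenase, had an amplitude of 0.40 (peak CT7.87) in Flox and 0.19 (peak CT15.6) in LKO (adjusted p = 0.0104), and Impa2, an inositol phosphatase, 0.12 and 0.44 (adjusted p = 0.0119). Bmf, Hps1, Rin2, Lhfpl2, Svil and Peli1 each had an adjusted p of 0.0119. Without the 6 LKO libraries none of these 8 passed, with 0.0538 for Cryl1 (range over its alternatives 0.000479 to 0.402) and 0.168 for Impa2 (3.83e-07 to 0.479). Leaving out CT42, CT44 or CT46 gave 7, 46 and 444 genes, leaving out CT8 gave 62, CT6 852, CT10 1129, CT32 1210 and CT38 1268, and leaving out CT18 or CT20 gave 3291 and 3300. The count was 0 without letter A and 0 without letter B, and the unadjusted count with all libraries was 3709. Of 5058 genes with a 24 h rhythm in the average of both genotypes, 36.8% had a lower amplitude in LKO, 54.0% of 4887 did without the 6 LKO libraries and 46.2% of 4220 without CT42 to CT46 in both genotypes.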

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

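Tests of the ribosomal RNA covariate and of the 12 h lists on each day were chosen before their results were seen, and the other tests of this part only afterwards. Of the genes named for the genotype comparison, 11 had a genotype effect that differed between CT0 to CT22 and CT24 to CT40 (limma interaction, two-sided, without CT42 to CT46). Between these windows the log2 difference of LKO from Flox changed by 5.54 for Scgb1c1 (SE 0.55, adjusted p = 2.60e-11), 3.96 for Ptgds (SE 0.43) and 3.06 for Mup6 (SE 0.32). It changed by 1.99 for Mia2 (SE 0.45), 1.71 for Ly6d (SE 0.38), 1.65 for Gstm3 (SE 0.28), 1.64 for Sprr1a (SE 0.32), 1.14 for Cyp2c29 (SE 0.37) and 0.84 for Ifi27l2b (SE 0.27, adjusted p = 0.00744). It changed by -1.85 for Fitm1 (SE 0.39) and -1.37 for Slc1a2 (SE 0.20). For Scgb1c1 the change was under way before CT24, as LKO libraries held at most 0.765 FPKM up to CT16 and from 0.327 to 20.5 at CT18 to CT22. Slc1a2 ran from 2.37 to 5.91 FPKM at CT18 to CT22, but some earlier LKO libraries were as low (from 4.00 to 18.6 FPKM up to CT16). One LKO library of CT24 to CT40 held 0.329 FPKM of Scgb1c1 and 8.12 of Slc1a2.

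Over all genes 5666 had a genotype effect that differed between these days, 4771 of them higher on the second, with female-biased genes moving most among the lists tested here. Female mice among the LKO libraries of CT24 to CT40 are argued against, since 0 of the 18 lacked the expression of Y-linked genes. Ribosomal RNA carried into the libraries does not account for the whole, because 83.8% of the 5666 remained with log2 Rn45s as a covariate. A lower share of hepatocytes would raise markers of other cells. The median change was 0.612 for Kupffer cell (15 of 15 above 0), 0.487 for endothelial (11 of 12) and 0.269 for stellate cell markers (10 of 11). It was 0.0994 for cholangiocyte (3 of 6) and 0.196 for hepatocyte markers (9 of 15). Most called genes rose as well (4771 of 5666), and the median over all genes is not given here. These medians therefore do not separate a change of cell share from a general shift. A lower share of hepatocytes stays open for the marker genes. It would not by itself raise female-biased genes, which are not markers of another cell type (median 2.22, 9 of 9 above 0, quartiles 1.65 and 2.42). Litters, ages or collection days that differ between time points within a genotype, and an effect of the deletion that differs among animals, could each explain the pattern and stay open, because the design gives 1 mouse set per time.

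The 6 LKO libraries of CT42 to CT46 hold 329 genes raised at least 8-fold to 10 FPKM or more, among them 21 of the 27 tested alveolar macrophage markers. More Kupffer cells are argued against, since the median log2 difference of 6 Kupffer genes was -0.0505, against 5.34 for the alveolar list. These 6 genes were picked after the data had been seen. The planned Kupffer list, which shares Marco and Lyz2 with the alveolar list, had a median of 0.161 (11 of 15 above 0). Some of its members rose far more, such as Cd68 (192 FPKM against 4.815 in Flox at the same times). For recruited monocytes the values do not decide. A set of 4 monocyte genes picked after the data had been seen had a median of 1.65. The planned list of monocyte-derived macrophage markers, which shares Itgax and Cd9 with the alveolar list, had 3.06 (8 of 8 above 0). Flox livers under an LKO label in all 6 are argued against too, since of 64 genes higher in LKO before CT42, 3 of the 6 held 27 or more above every Flox library and past 8 times the least that a fixed mixture brought, which at most 3 of the 329 raised genes passed, while no Flox library had more than 14 above all others. The other 3 held 1 to 12. As 8 of 42 LKO libraries before CT42 also scored within the Flox range, Flox livers under these 3 labels stay open. Rbbp5 measured 3.79 FPKM in the 6 against 2.71 in Flox. Of the 6, 5 scored above every Flox library with the added RNA included. Slc1a2 (0.434 to 5.98 FPKM in the 6) lay below its lowest Flox value of 6.83, but hepatocyte markers were lower there as well (median log2 difference -0.662). These values therefore do not decide for the 3 labels. The raised genes kept their ratios across the 6 libraries, with a median SD of log2 ratios of 0.387 over the 15 pairs against 0.549 for genes of like level (lower in 14 pairs), so RNA of another source, such as lung macrophages, added in 1 fixed mixture may explain them, while a change of liver macrophages themselves stays open as untested.

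The 12 h rhythms of LKO were examined for their source. Of the 933 calls 0.214% remained without the 6 LKO libraries of CT42 to CT46, which is consistent with these libraries as a candidate explanation for the calls. For Flox, the 3 list scores were tested on each day, and the highest of their 6 unadjusted permutation p-values was 0.0299. The lists were chosen for a 12 h rhythm over the same libraries, which favours small p-values on single days. Rhythms carried by 1 of the 2 days are therefore not excluded. A 12 h rhythm of the list scores that is weaker in LKO stays a hypothesis, since the difference did not pass after adjustment.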

How the results depend on the processing

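Settings without the 6 LKO libraries or without CT42 to CT46 in both genotypes, and the trend and Rn45s settings joined to the former, were chosen only after the data had been seen. Of 116 named genotype differences, 72 kept direction and call in every alternative run, 41 lost the call in some and 5 turned in some, with overlap. None of the 18 named 12 h amplitudes in Flox kept the call state in every alternative, and of 12 in LKO only Xbp1, Hspa5 and Atf6 did, which had no call to lose. Of the 23 named 24 h amplitudes in Flox 20 kept it, of 17 in LKO 13 did, and of 8 named 24 h differences 0 did. Absolute depth is unknown, so no depth limit of single values is given. Where no reason is given for a change, the cause was not tested.

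Below, counts are of genes higher and lower in LKO (3897 and 1896 as reported), with a 12 h rhythm in Flox (176) and LKO (933), with a 24 h rhythm in Flox (2699) and LKO (4901), and with a different 12 h (0) or 24 h rhythm (1968), followed by the shares with a lower amplitude in LKO (54.1% at 12 h, 36.8% at 24 h). Values not listed stayed within 1.5 times. Requiring an absolute log2 fold change of 0.58 gave 572 higher and 198 lower, by construction fewer. An adjusted p under 0.01 gave, also by construction, 58 and 29 for 12 h, 1477 for 24 h in Flox and 1 for the 24 h difference. Quantile normalization gave 3535 lower, 1481 for 12 h in LKO, 4 and 998 for the differences and 40.1% at 12 h. Median-ratio size factors gave 1 and 1110 for the differences and 44.5% at 12 h.

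The first day alone, with fewer libraries, gave 2504 higher, 4366 lower, 24 and 7 for 12 h, 1431 for 24 h in LKO, 0 for the 24 h difference and 56.8% at 24 h. It turned the log2 fold changes of Cyp3a41a (-0.0715), Cyp17a1 (-0.0866), Cyp3a16 (-0.0563) and Arg1 (0.0276). The second day alone gave 900 lower, 2132 and 3367 for 12 h, 4633 and 4813 for the differences, 20.2% at 12 h and 23.6% at 24 h, and turned Gldc (0.0733). Library weights, whose estimation stopped before convergence, gave 4676 for 12 h and 6416 for 24 h in Flox, 4025 and 1046 for the differences and 49.4% at 24 h. A separate fit per genotype gave 737 and 0 for 12 h and 4703 for 24 h in Flox. Time point means, with fewer values, gave 23 and 0 for 12 h, 1319 and 3007 for 24 h, 0 for the 24 h difference and 74% at 12 h, and 0 list scores differed in their 12 h rhythm, a test added after the data had been seen. Ranks gave 282 and 31 for 12 h, 4362 and 3085 for 24 h, 14 for the 24 h difference and 56.6% at 24 h. A linear trend gave 208 for 12 h in LKO and 4 for the 24 h difference. In place of 12 h, a period of 10 h gave 0 and 0 genes, 11 h 4 and 0, 14 h 2 and 0, and 13 h 392 in LKO. The fitted 24 h amplitude of Rora in LKO (0.03, not past the threshold) turned in phase after quantile normalization (0.0736), on the second day (0.0731), without letter B (0.160) and without CT10 (0.0142), and it ranged from 0.00764 without CT8 to 0.196 without letter A.

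Without the 6 LKO libraries there were 2970 lower, 4 for 12 h and 2647 for 24 h in LKO, 26 for the 24 h difference and 54.0% at 24 h. Without CT42 to CT46 in both genotypes these were 3030, 11, 2918 and 30, with 68.4% at 12 h and 46.2% at 24 h. With a linear trend added to the former, 12 h gave 344 and 64, 24 h in LKO 2216, the 24 h difference 7 and the share 56.2%. With log2 Rn45s as a covariate these were 353, 9, 2951, 59 and 51.5%, with 3584 higher, 1306 lower, 15 lists higher and 11 lower.

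Leaving out letter B took out 48 of the 96 libraries and left each genotype with 1 library per time point. Leaving out A took out 44, and C 4. A single library is assumed to vary like the others. Leaving out 1 letter gave 2077 to 3900 higher, 788 to 1854 lower, 6 to 156 and 0 to 831 for 12 h, 595 to 2230 and 2060 to 4799 for 24 h, 0 to 1718 for the 24 h difference and 63.2% to 87.5% at 12 h. List scores with a 12 h rhythm in Flox then numbered 0 to 3, and differing ones 0 to 1. Leaving out 1 time point gave 3567 to 4112 higher, 1661 to 2108 lower, 2130 to 3488 and 3612 to 5670 for 24 h, 81 to 472 and 7 to 2042 for 12 h, 0 to 2016 and 7 to 3300 for the differences and 33.6% to 69.3% at 12 h, with shares of 46.6% without CT14, 43.4% without CT18, 33.6% without CT20 and 47.7% without CT22. Camera with an estimated correlation called 0 lists higher and 0 lower, and quantile normalization gave 2 list scores with a 12 h rhythm in LKO.

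A replicate block of time and letter, for which the letters' pairing was tested, gave 3633 higher, 1769 lower, 0 and 1398 for the 12 h and 24 h differences and 12 lists higher and 13 lower. Each of the 128 named results that the block can test kept its direction and call. Tests of other periods and within 1 genotype could not be run under the block, since it absorbs time.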

Other observations

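The groupings and the tests of the added lists were chosen only after the results were seen. Antioxidant and sterol genes moved within lists that did not pass as a whole, and the counts of members here are the same adjusted over the list alone unless given. Of 22 glutathione and NRF2 target genes 13 rose and 4 fell, among them the glutathione transferases Gstm1 (997 ± 284 to 1666 ± 443 FPKM, SD, n = 48) and Gstm2 (1.16, SE 0.11, higher at 24 time points), with camera adjusted p = 0.0892 (0.0138 without the 6 LKO libraries, range over its alternatives 9.87e-06 to 0.582). Of 25 cholesterol synthesis genes 8 rose and 4 fell (adjusted p = 0.605), with Hmgcs1, an early enzyme of the pathway, at 38.04 and 60.3 FPKM and the sterol carrier Stard4 lower by a log2 value of -0.71. Of 40 ER chaperone and degradation genes 8 rose and 10 fell (adjusted p = 0.143), among them Herpud1, which serves ER-associated degradation (126 to 81.0 FPKM, -0.71, SE 0.11), and Fkbp11 (0.84, SE 0.15). Of 18 genes of H3K4 methyltransferase complexes, to which RBBP5 belongs, 5 rose and 1 fell (adjusted p = 0.796), with Kmt2a at 0.29 (SE 0.06) and Setd1a at 0.31 (SE 0.09), and of 5 H3K4 demethylases Kdm1a rose (0.20, SE 0.05, list adjusted p = 0.913). With the 6 LKO libraries left out, the counts of genes that rose and fell were 12 and 3 for glutathione, 8 and 5 for cholesterol synthesis, 7 and 14 for ER chaperones, 2 and 6 for H3K4 methyltransferases and 1 and 1 for H3K4 demethylases.

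Other planned lists did not pass camera. Of 56 oxidative phosphorylation genes 21 rose and 15 fell (adjusted p = 0.508), of 56 ER translocation and transport genes 13 rose and 8 fell (12 and 7 adjusted over the list alone, 0.245), of 32 ribosome biogenesis genes 12 rose and 1 fell (0.427) and of 20 cytosolic heat shock genes 2 rose and 3 fell (2 and 2 adjusted over the list alone, 0.214). Of 17 core clock genes 4 rose and 4 fell (0.235), with Per2 at 0.34 and Hlf at -0.31. Leaving out the 6 LKO libraries gave 28 and 15, 10 and 21, 8 and 6, 1 and 8 and 3 and 6 genes higher and lower in these 5 lists. Erythroid (0.247) and extrahepatic tissue markers (0.644) did not pass, and of the B and plasma cell list 1 of 13 genes was tested. P-values of the added lists were adjusted over the added lists only, not over the 43. Among the added lists, ribosomal RNA precursor and small nucleolar RNA genes had 3 of 9 higher (adjusted p = 0.613, and 4 higher without the 6 LKO libraries) and Y-linked genes 0 of 3 (adjusted p = 0.72). The added alveolar macrophage list, picked for its rise in the 6 LKO libraries, passed with them (23 of 27 higher, adjusted p = 0.00199, and 0.809 with an estimated correlation) and without them (15 higher and 4 lower, adjusted p = 0.0137, and 0.408 with an estimated correlation). Camera compares a list with all other genes, and its direction was lower, against a median above 0, for both H3K4 lists (medians 0.05 and 0.05), oxidative phosphorylation (0.09), cholesterol synthesis (0.10) and extrahepatic markers (0.17). The core clock and heat shock lists had a lower direction and median but means of 0.00 and 0.03. Rn45s measured 4500 FPKM in LKO and 1407 in Flox at CT0 to CT22.

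Letters did not pair the libraries of both genotypes, as shown by the difference between both letters at 1 time point, correlated across genes between Flox and LKO. Over the 20 time points with the same letters in both genotypes this correlation had a median of 0.0463 and a range from -0.402 to 0.338, and it exceeded 0.1 at 7. These correlations run across genes, which are not independent replicates. No library pair was a copy in its values, as the highest share of identical values was 0.263%. The highest correlation across genes, with the mean of each gene removed, was 0.985, between the LKO libraries of CT42. These libraries are therefore close, and whether they share a source was not tested.

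Genotype labels were regrouped within time points 100 times, the real grouping included. For the 3897 genes higher no other grouping called as many (1 grouping as large, highest other 17). Few groupings were as large for the 1896 genes lower (2 groupings, highest other 2379). The same held for the 24 h differences of 1968 genes (2 groupings, 2223) and of 30 genes without CT42 to CT46 (2 groupings, 1060). In each of these cases another grouping called more genes than the real one, so chance is not excluded. The last of these, with a grouping that called several times the real count, may point to a structure of the samples beyond genotype, which was not tested. For the 12 h difference of 0 genes the groupings decide nothing, since no count is lower (100 groupings, highest other 0). Chance cannot be excluded for the share of 54.1% (86 groupings, farthest other 80.2%), that of 68.4% without CT42 to CT46 (18 groupings, farthest other 11.5%) or that of 36.8% at 24 h (34 groupings, farthest other 22.99%). Nor can it for the 13 lists higher (23 groupings, highest other 20) and the 13 lower (19 groupings, 20).

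Time points were shuffled within genotypes 100 times, the real order included. For 24 h rhythms in Flox no other order called as many genes (2699 genes, 1 order as large, highest other 2577). In LKO few orders were as large, but another order called more than the real one (4901, 3 orders, 5588), so chance is not excluded there. Chance cannot be excluded either for the number of 12 h rhythms in Flox (176, 9 orders, highest other 3572) or in LKO (933, 33 orders, 5243). Orders that called several times the real 12 h counts may point to a structure of the samples over time, which was not tested, so the 12 h counts by themselves do not separate a 12 h rhythm from other changes over time.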
